A study of Homo sapiens with 12 samples.

How the data were processed

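The series holds peak lists of 12 ChIP-seq libraries of LNCaP cells: 4 with an antibody against HA (5 days after infection, 1 library per condition) and 8 with an antibody against FOXA1 (7 days of treatment, 2 per group). Per the labels' protocols, chromatin was sheared by sonication and single-end reads were made on an Illumina instrument. Per the submitters' processing notes, Bowtie2 and HOMER 4.2 were used with the genome build hg19. Per the file headers, peaks were called in each library separately with HOMER findPeaks in factor mode, at a false discovery rate of 0.001, with at least 4-fold more tags than a local window of 10 kb and a Poisson p of 0.0001 for that excess. Per the file headers, the FOXA1 lists were also filtered against an input library, at the same 4-fold and p, and each treatment has 1 input that serves both of its replicates; the HA lists were called without input. Peaks have a fixed width within a library, set by HOMER: 233 to 304 bases for HA and 274 to 365 bases for FOXA1.

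The deposited normalized tag count of each peak is a signal value, the tags in the peak scaled to a library of 1e7 tags, per the file headers. The deposited findPeaks score of each peak was used only for a stricter threshold (17 for HA and 20 for FOXA1, the medians of the pooled WT and K295A lists and of the pooled FOXA1 lists). The deposited fold over the local window and the fold over input are the peak caller's own ratio for each peak and serve here to describe lists and to recover input tags. The deposited total tag count per peak is a whole-number count and was given for DMSO replicate 1, EPZ-6438 replicate 2 and combination replicate 2, per the file headers. Multiplying each normalized tag count by the library total recovered whole tags for 100% of peaks within print rounding, and these equalled the deposited count for 97.3%, 100% and 100% of peaks in those 3 libraries. The recovered tags were used for edgeR.

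FOXA1 peaks of all 8 libraries were merged where they shared at least 1 base, which gave 140968 regions with a median width of 386 bases. Each library was given the tag count of its highest peak in a region. The main test of tag counts used limma (version 3.58.1, trend on, R 4.3.3) on log2 (tag count + 1) at the 24242 regions called in all 8 libraries, with the 4 groups in the model and Benjamini-Hochberg adjustment at 0.05. When nothing changes, a share of 0.05 of the tested regions is expected at an unadjusted p under 0.05. A count below that share is no sign of a change. Differences are on the log2 (tag count + 1) scale, which understates changes of weak regions. A region that gains or loses its peak altogether is not among those tested and was counted as lost or gained, that is called in both libraries of one condition and in neither of the other. Peak numbers and median tag counts were compared by exact permutation tests, two-sided. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples. For HA, with 1 library per condition, no test was run; overlaps of at least 1 base are given with 95% exact (Clopper-Pearson) intervals and beside 100 circular shifts of a list within each chromosome. Intervals cover counting error only.

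Replicate numbers come from the titles. Whether they pair the libraries was checked from deviations of replicate 1 from its group mean over the tested regions: their correlations between groups were 0.148 to 0.488, all 6 above 0.1. The file headers show the same split, with fragment lengths of 274 to 278 bases in replicate 1 and 216 to 230 in replicate 2. Fits with the replicate number as a block are therefore given beside the results they change. The block alone changed no count of regions from 0.

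The limma step was tested on simulated data with the spread of the real regions and 100 regions made 2-fold and 100 made 4-fold higher among 24242. For EPZ-6438 against DMSO the planned fit found 0 of each; the fit with replicate block and centring found 2 and 61. For all libraries with EPZ-6438 against all without, the planned fit found 0 and 41, and the blocked and centred fit 45 and 91, with 5 false calls. The simulated noise was independent between regions and libraries, with no shift of whole libraries and no replicate effect. The numbers of found and false calls therefore need not hold for the real libraries. The overlap, merging and correlation steps were also tested on simulated data with known answers.

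Alternatives fixed before the data were examined were a stricter score threshold, other definitions of overlap, equal numbers of top peaks, leaving out background peaks, the replicate block, centring on the median, quantile normalization, a pseudocount of 5, regions called in at least 4 libraries, the upper part of mean tag counts, edgeR (version 4.0.16, quasi-likelihood), the libraries of each contrast alone and leaving out each library. Added after seeing the data were the block together with centring, with quantile normalization or with TMM factors, the region by region comparisons of all libraries with a compound against all without it and of the treatments with each other, removal of each library's trend on mean tag count, tags per 300 bases of peak, and lost and gained regions with no peak of the other condition within 1000 bases. Regions named in the text follow a rule fixed beforehand. In each tag count comparison they were the 5 largest rises and falls past the threshold. Where fewer than 3 passed, they were the 3 with the smallest p, said not to pass where they did not. Against DMSO, both treated libraries also had to lie on the same side of both controls. That condition was not applied to the other comparisons, so the libraries compared can overlap at a region named there. For HA they were the 5 strongest regions outside the untagged lists, called with both proteins and with each alone. For calls they were the 5 strongest lost and gained regions per treatment. Other regions are said to be chosen after their values were seen. Gene names, gene list tests, peak annotation and motif searches need an annotation or sequence of hg19 and were not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.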

Results

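Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in LNCaP cells, an androgen-responsive human prostate cancer cell line, to map the genomic occupancy of FOXA1, a forkhead pioneer transcription factor of luminal prostate cells. The series title places the experiment in a study of how Polycomb and a BUB3/USP7 deubiquitinating complex regulate FOXA1 protein stability. In the first experiment an antibody against the HA tag was used 5 days after infection, with 1 library for each of 4 conditions: a pGIPZ control, a short hairpin against FOXA1 (shFoxA1), and shFoxA1 together with HA-tagged wild-type (WT) FOXA1 or with HA-tagged FOXA1 carrying the K295A substitution. The first 2 conditions carry no HA tag by their labels and give the background of the antibody. In the second experiment endogenous FOXA1 was precipitated after 7 days with DMSO (the solvent control), 1 µM EPZ-6438 (tazemetostat, an inhibitor of the Polycomb methyltransferase EZH2), 3 µM P5091 (an inhibitor of the deubiquitinase USP7) or both, with 2 libraries per group. Total tags per library ranged from 11640056 to 13694090 for HA and from 12299238 to 22589685 for FOXA1. Regions are given by hg19 coordinates, and genes near them were not analysed here. FOXA1 protein and RNA levels were not analysed here either, so the knockdown itself was not checked.

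HA-tagged FOXA1 was found at far more sites than the background of the untagged libraries, and the K295A protein occupied largely the same sites as WT, with nearly the same signal at the sites called with both. The WT library held 97120 peaks and the K295A library 81607, against 982 in the pGIPZ control and 971 with shFoxA1 alone. The tag threshold at the false discovery rate was 10 for WT and 11 for K295A, which admits more weak peaks with WT. Peaks took 20.5% of all tags with WT and 17.7% with K295A, and 0.64% and 0.66% in the untagged libraries. Of the K295A peaks, 83.2% overlapped a WT peak (95% exact binomial interval 83.0 to 83.5) and 69.9% of the WT peaks overlapped a K295A peak (69.7 to 70.2), whereas circular shifts of the lists along each chromosome gave medians of 2.0% and 1.67%. When both lists were limited to their strongest 81607 peaks, 77.0% of each overlapped the other. Every condition has 1 library, so none of these differences has a replicate check, and the intervals cover counting error only.

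Outside the untagged lists, 67500 regions were called with both proteins, 29089 with WT alone and 13553 with K295A alone. The shared regions were the stronger ones, with a median normalized tag count (tags scaled to a library of 1e7 tags) of 19.1 in the WT library, against 11.4 at regions called with WT alone. The K295A library gave 17.3 at shared regions and 11.3 at regions called with K295A alone. At the shared regions the log2 ratio of K295A over WT had a median of -0.086 (quartiles -0.36 and 0.20), and 97.48% of them lay within 2-fold of each other; regions called with a single protein have no value for the other and are not part of this comparison. The tag count was at least 2-fold lower with K295A at 1236 regions and at least 2-fold higher at 468. How many such departures counting error alone would give was not computed. The log2 tag counts of the libraries correlated across regions with Pearson r = 0.844; regions are not independent replicates.

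Outside the untagged lists, the 5 strongest regions called with both proteins gave ratios of 0.891 to 1.21. At chr10:42385062-42385369 the tag count was 983.8 with WT and 1186.4 with K295A, a ratio of 1.21 (95% counting interval 1.12 to 1.30), and 4 of the 5 strongest lay on the unplaced contig Un_gl000220, with ratios between 0.891 and 0.993. None of these 5 was a region called in both DMSO libraries of the FOXA1 experiment. The HA lists were called without input, and no region was left out for repeated sequence. These 5 therefore say little about the occupancy of K295A against WT. Among shared regions that were also called in both DMSO libraries, chosen after their values were seen, the strongest was chr9:68420566-68420873, with 327.4 for WT and 292.3 for K295A (ratio 0.893, 0.776 to 1.03). At chr5:173574080-173574401 the values were 293.8 and 268.9 (ratio 0.915, 0.790 to 1.06), and the widest departure among the leading 5 was at chr2:242032828-242033155, with 222.9 and 285.5 (ratio 1.28, 1.097 to 1.497).

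Outside the untagged lists, the strongest regions called with WT alone were chr18:18519209-18519513, with a WT tag count of 351.1, and chr1:8319158-8319462, with 109.9. The same limit on repeated sequence applies here. Those called with K295A alone were Un_gl000220:113552-113850, with a K295A tag count of 741.2, chrX:58561270-58561568, with 119.0, and chr1:8319712-8320010, with 117.5. The pair on chromosome 1 lies less than 1000 bases apart, and whether these are separate sites or a moved summit was not tested. A peak of the other library lay within 1000 bases of 2168 of the regions called with WT alone and of 1884 of those called with K295A alone. The remaining 26921 and 11669 regions had no peak of the other protein within that distance, and the 5 strongest of these with each protein lay outside the regions called in both DMSO libraries.

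**Figure D1:**
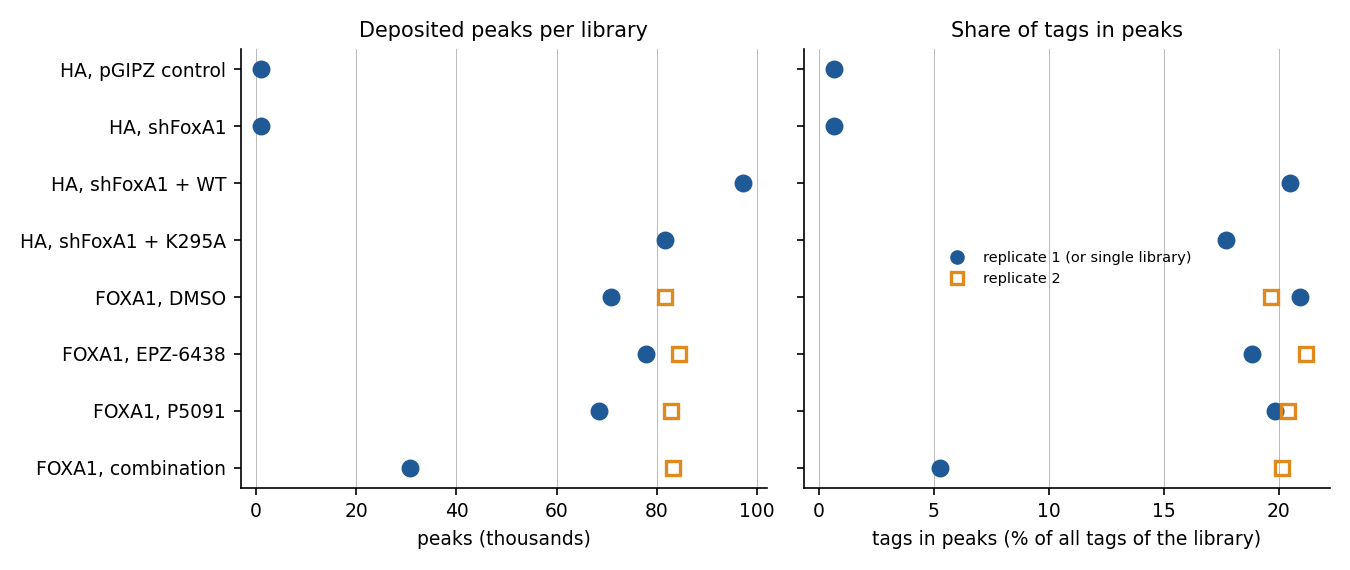
Peaks per library (left, axis in units of 1000 peaks) and the share of all tags that fall in peaks in percent (right) for the 4 HA and 8 FOXA1 libraries, with a point for each library. The untagged HA libraries sit at 982 and 971 peaks, and replicate 1 of the combination, with 30811 peaks and 5.26% of tags in peaks, lies apart from the other 7 FOXA1 libraries.

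Both tagged proteins covered most of the sites of endogenous FOXA1. Of the 24242 regions called in all 8 FOXA1 libraries, 91.3% overlapped a WT peak and 90.7% a K295A peak, against 0.03% and 0.02% for the pGIPZ control and shFoxA1 libraries. Of the 57311 regions called in both DMSO libraries, 74.2% overlapped a WT peak and 71.1% a K295A peak. In the other direction, 43.8% of the WT peaks (43.5 to 44.1) and 49.9% of the K295A peaks (49.6 to 50.3) overlapped a region called in both DMSO libraries, with chance medians of 1.43% and 1.42%. For the pGIPZ control and shFoxA1 lists the shares were 2.04% and 2.47%, beside chance medians of 1.22% and 1.13%. The shared HA regions were called in both DMSO libraries in 54.9% of cases, the regions called with WT alone in 18.7% and those called with K295A alone in 27.2%. The lists were made with different antibodies and without an input library for HA.

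**Figure D2:**
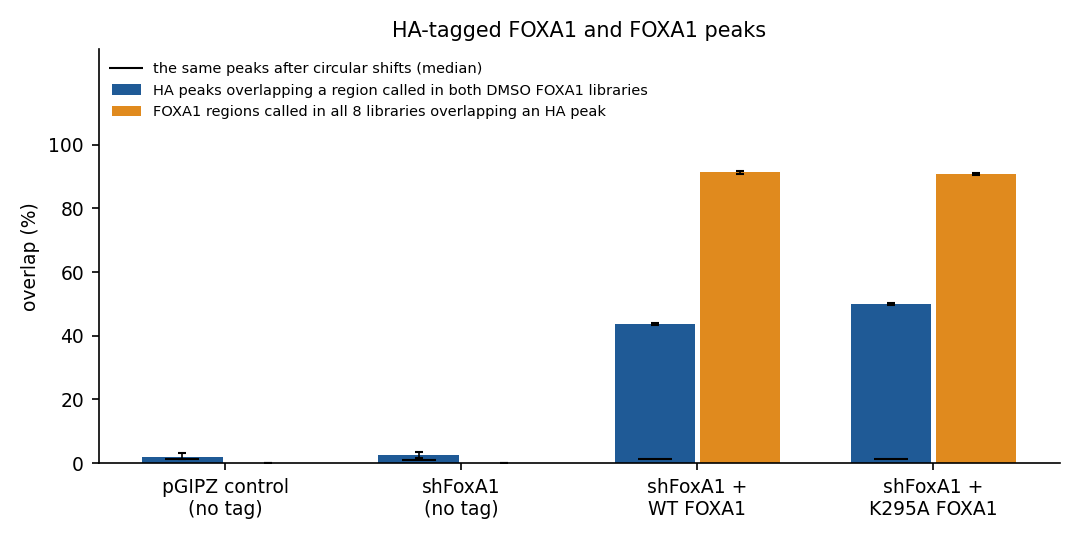
Overlap in percent between HA peaks and endogenous FOXA1 regions, for the 4 HA libraries; bars are shares of the HA peaks (blue) and of the FOXA1 regions called in all 8 libraries (orange), error bars are 95% exact binomial intervals for counting error, and black lines are medians over 100 circular shifts. WT and K295A reach 91.3% and 90.7% of the FOXA1 regions, and the untagged libraries 0.03% and 0.02%.

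Neither the number of FOXA1 sites called nor their typical signal differed between a compound alone and DMSO in a way these tests could separate from the spread between libraries. Peak number was 76160 ± 7567 (SD, n = 2) with DMSO, 81102 ± 4697 with EPZ-6438, 75665 ± 10127 with P5091 and 57003 ± 37040 with the combination. The differences from DMSO in mean log2 peak number were 0.093 for EPZ-6438 (exact permutation p = 0.667, two-sided), -0.012 for P5091 (p = 1, exact) and -0.59 for the combination (p = 1, exact). The median log2 tag count over the 24242 regions called in all 8 libraries differed from DMSO by -0.056 with EPZ-6438 (p = 0.667), -0.002 with P5091 (p = 1) and -0.68 with the combination (p = 0.667), all by exact permutation. With 2 libraries against 2, no p below 0.33 can be reached. Within replicate numbers, peak number with EPZ-6438 was higher than with DMSO in both, by 0.135 and 0.051 (exact sign-flip permutation p = 0.5, two-sided, the smallest possible), and with P5091 it differed by -0.048 and 0.023. Over the layout of both compounds, with 4 libraries against 4, the median tag count differed by -0.36 for EPZ-6438 (p = 0.171) and -0.31 for P5091 (p = 0.543), and peak number by -0.24 (p = 0.886) and -0.34 (p = 0.486), again by exact permutation. Combination replicate 1 carries most of these differences: without it they were -0.058 and 0.005 for tag count and 0.112 and -0.011 for peak number.

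The lower values of the combination came from replicate 1 alone. That library held 30811 peaks where the other 7 FOXA1 libraries held 68504 to 84423, and 5.26% of its tags lay in peaks against 18.9% to 21.2%. Its median tag count at the common regions was 15, against 40.2 for DMSO replicate 1, a log2 difference of -1.36. Its peaks were also narrower (279 bases against 365), and per 300 bases of peak, an alternative added after seeing the data, the combination differed from DMSO by -0.45 in place of -0.68. Replicate 2 of the combination gave 36.3 against 36 for DMSO replicate 2, a log2 difference of 0.012, and the peak number differed by -1.20 in replicate 1 and 0.029 in replicate 2 on the log2 scale. For EPZ-6438 the tag count differences were -0.20 and 0.083 in replicates 1 and 2, and for P5091 they were -0.061 and 0.057. Of all 140968 merged FOXA1 regions, 13487 were called in each of the other 7 libraries and not in combination replicate 1.

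At single regions, no difference in FOXA1 signal between EPZ-6438 and DMSO passed the test fixed before the data were examined. limma called 0 of 24242 regions between EPZ-6438 and DMSO, with 233 at an unadjusted p under 0.05. On the tags recovered from the deposited values, edgeR called 0, with 255 unadjusted. Both unadjusted counts lie below the share of 0.05 of the tested regions expected when nothing changes. The smallest p among higher regions was at chr9:19698945-19699420, with tag counts of 9.51 and 6.39 with DMSO and 21.2 and 38.2 with EPZ-6438 (log2 difference 1.74 ± 0.47 SE, adjusted p = 1). Also higher without passing were chr1:214248615-214249055 (11.0 and 7.55 with DMSO, 37.2 and 30.1 with EPZ-6438) and chr13:78450182-78450602 (14.6 and 6.97, then 29.7 and 48.8). At these higher regions the values of DMSO replicate 2 lay near its calling threshold of 11 tags in 17225421. Lower without passing were chr15:48828949-48829398 (37.3 and 18.6 with DMSO, 9.30 and 8.13 with EPZ-6438), chr2:99321208-99321608 (76.8 and 57.5, then 27.4 and 9.76) and chr7:72218832-72219246 (64.4 and 48.8, then 20.4 and 12.2). At the regions on chromosomes 15 and 2 the values of EPZ-6438 replicate 2 lay near its calling threshold of 10 tags in 12299238. The test had little reach here: in simulated libraries with independent noise of the same spread it found 0 of 100 regions made 4-fold higher in this comparison.

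Fragment lengths separated the replicate numbers (274 to 278 bases against 216 to 230), and the median residual SD fell from 0.519 in the planned fit to 0.322 once each library was centred on its median. With the replicate number as a block and each library centred on its median, a fit chosen after seeing the data, limma called 78 regions higher and 89 lower with EPZ-6438 than with DMSO, and edgeR with the block and TMM factors called 210 and 181. The largest rise and fall among them were at chr13:78450182-78450602 (log2 difference 1.87 ± 0.36 SE, adjusted p = 0.00344) and chr2:99321208-99321608 (-1.89 ± 0.31, adjusted p = 0.000777). This count fell to 0 without DMSO replicate 2 or without EPZ-6438 replicate 2, to 5 without EPZ-6438 replicate 1 and to 48 without DMSO replicate 1, each by limma, with 1887, 2100, 2213 and 2687 regions at an unadjusted p under 0.05. It rose to 482 without combination replicate 2, and to 610 without combination replicate 1, where 37729 regions could be tested. With the block it was 177 once the trend on mean tag count was removed and 34 with quantile normalization, and centring without the block gave 0 by limma, with 1595 unadjusted.

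P5091 left no region past the threshold in the planned fit, and none with replicate block and centring. limma called 0 regions between P5091 and DMSO, with 12 at an unadjusted p under 0.05, and edgeR called 0, with 13 unadjusted. The fit with replicate block and centring called 0, with 537 unadjusted. All of these unadjusted counts lie below the share of 0.05 of the tested regions expected when nothing changes. The regions with the smallest p that were higher with P5091 included chr18:61676441-61676898, with tag counts of 7.31 and 6.39 with DMSO and 13 and 15.7 with P5091 (log2 difference 0.96 ± 0.41 SE, adjusted p = 1), and chr2:147844941-147845464 (9.51 and 8.13, then 18.9 and 20.6). Those lower with P5091 included chr9:122817770-122818184, with 24.9 and 14.5 with DMSO and 13 and 6.66 with P5091 (log2 difference -0.95 ± 0.43 SE, adjusted p = 1), and chr11:78494834-78495209 (27.1 and 23.2, then 13 and 11.5). None of these regions passed. Values near the calling threshold of their library lay on both sides, with 7.31 and 6.39 for DMSO and 6.66 for P5091 replicate 2.

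With the combination the tested regions were shifted down as a whole by a median log2 difference of -0.69, nearly all of it from replicate 1, and no region passed in the planned fit. limma called 0 regions, with 3415 at an unadjusted p under 0.05, and edgeR called 0, with 2438 unadjusted. The lowest p was at chr9:110146885-110147285, with tag counts of 147.7 and 80.1 with DMSO and 18.1 and 18.9 with the combination (log2 difference -2.49 ± 0.59 SE, adjusted p = 0.31). Among higher regions it was at chr4:81630615-81631049, with 14.6 and 6.97 with DMSO and 20.6 and 45.8 with the combination (1.51 ± 0.53, adjusted p = 0.348). Relative to the shift of each library, with replicate block and centring, 437 regions were higher and 588 lower than with DMSO, and edgeR with the block and TMM factors gave 377 and 404. With each library's trend on mean tag count removed, the limma count fell to 547 and the balance turned, with 298 higher and 249 lower, and centring without the block gave 0 by limma, with 2768 unadjusted. The count of 1025 was 49 without DMSO replicate 2, 270 without DMSO replicate 1, 209 without combination replicate 1 and 1878 without combination replicate 2. In the planned fit, leaving out combination replicate 2 gave 16154 regions, of which 16151 were lower, since replicate 1 then stood alone for the treatment.

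Whether the compounds act beyond the sum of each was asked with the interaction of EPZ-6438 and P5091. limma called 0 regions, with 158 at an unadjusted p under 0.05, and 0 with replicate block and centring, with 813 unadjusted. With the block and TMM factors edgeR called 0, with 833 unadjusted. Each of these unadjusted counts lies below the share of 0.05 of the tested regions expected when nothing changes. The smallest p was at chr9:89900129-89900568, where tag counts were 21.2 and 8.13 with DMSO, 31.0 and 29.3 with EPZ-6438, 26.1 and 20 with P5091 and 8.13 and 12.6 with the combination (interaction -2.23 ± 0.71 SE, adjusted p = 0.875). Without combination replicate 2 the planned fit gave 5912 regions, all lower, which rest on combination replicate 1.

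Comparing all 4 libraries with EPZ-6438 against all 4 without it, 846 regions rose and 982 fell relative to the median of each library. This comparison was added after seeing the data and used limma with the replicate block and centred libraries at 24242 regions, so the balance of rises and falls depends on the centring; uncentred, the median difference was -0.38, and -0.086 without combination replicate 1. The regions that rose had a median over regions of the mean tag count of 27.4, and those that fell 55.7, against 34.7 for all tested regions. With each library's trend on mean tag count removed, 750 regions were higher and 609 lower and these medians were 35.2 and 43.9, so much of the contrast between weak and strong sites went with the trend. Among the 846 and 982 regions of the centred fit the median rise was 0.82 and the median fall -0.67 on the log2 scale. Of the regions that fell, 98.2% held the centre of an HA-tagged WT peak, against 80.0% of those that rose and 91.0% of all tested regions, and with the trend removed the shares were 96.6% and 86.1%. For P5091 the same comparison called 0 regions by limma, with 1041 at an unadjusted p under 0.05. By edgeR with the block and TMM factors it called 0, with 1062 unadjusted. These unadjusted counts, too, lie below the share of 0.05 of the tested regions expected when nothing changes.

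The largest rise was at chr12:39285810-39286319, with tag counts of 10.2 and 14.5 with DMSO and 9.13 and 30.3 with P5091, and of 42.9 and 43.9 with EPZ-6438 and 18.1 and 53.7 with the combination (log2 difference 1.67 ± 0.24 SE, adjusted p = 9.09e-06). At chr18:28030822-28031214 DMSO gave 15.4 and 15.7, P5091 12.4 and 35.1, EPZ-6438 42.9 and 57.7 and the combination 23.1 and 67.9 (1.62 ± 0.22, adjusted p = 3.96e-06). In the same order, chr8:56597963-56598392 gave 21.2 and 11.0, 20.9 and 32.7, 50.5 and 60.2, and 25 and 66.3 (1.57 ± 0.22, adjusted p = 3.96e-06). At these regions and at the one on chromosome 12, P5091 replicate 2 lay above combination replicate 1 as deposited. The other leading rises were at chr4:81630615-81631049 (1.6) and chr18:35620739-35621147 (1.55). The largest fall was at chr9:110146885-110147285, from 147.7 and 80.1 with DMSO to 55.3 and 26.0 with EPZ-6438 (-1.53 ± 0.18, adjusted p = 2.34e-08). At chr3:176477688-176478096, a strong region, DMSO gave 255.2 and 202.6 and P5091 232.2 and 122.3, while EPZ-6438 gave 97.8 and 63.4 and the combination 37.5 and 52.9 (-1.34 ± 0.15, adjusted p = 6.24e-09). Further falls were at chr2:100314106-100314606 (-1.39), chr13:90956856-90957314 (-1.36) and chr2:99321208-99321608 (-1.33), the last of which passed only with the replicate block.

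**Figure D3:**
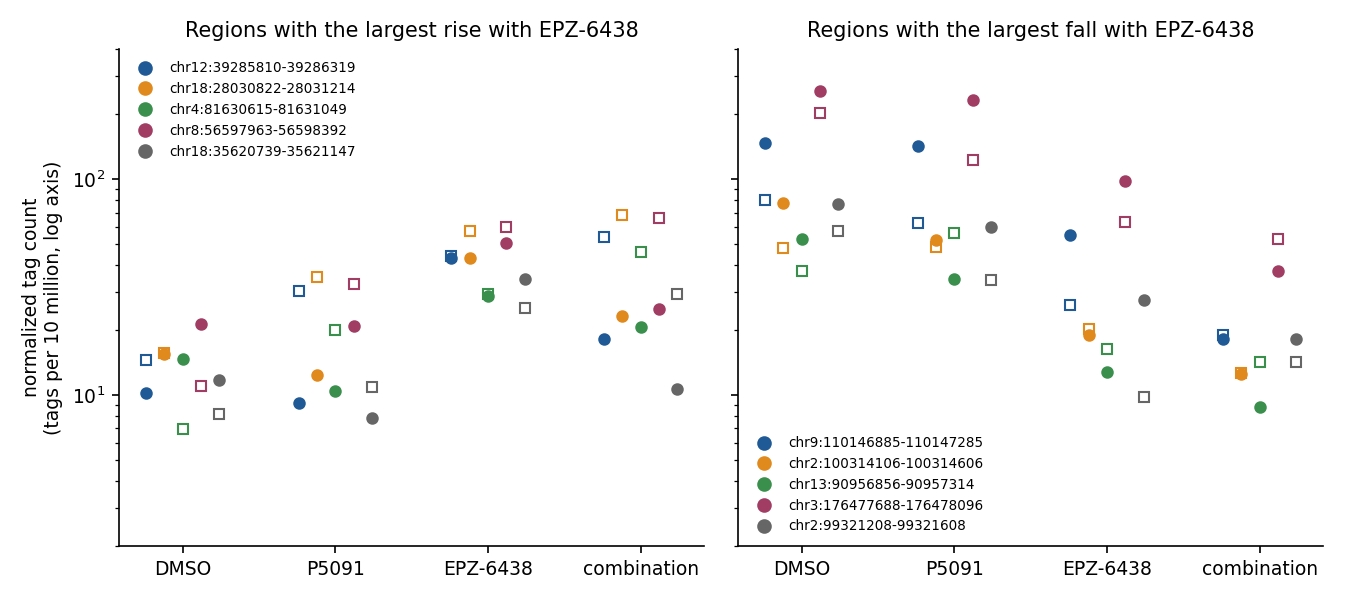
Normalized tag counts (scaled to 1e7 tags, log axis) at the 5 regions with the largest rise (left) and the 5 with the largest fall (right) with EPZ-6438, in the 4 treatment groups; filled circles are replicate 1, open squares replicate 2 and each colour is a region. At chr3:176477688-176478096 the libraries without EPZ-6438 lie between 122.3 and 255.2 and those with it between 37.5 and 97.8. At chr12:39285810-39286319 they overlap, with 30.3 in P5091 replicate 2 and 18.1 in combination replicate 1.

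The EPZ-6438 differences correlated weakly between sets of libraries with none in common, and those of P5091 showed no such recurrence. The change over DMSO in replicate 1, the change over DMSO in replicate 2 and the change of the combination over P5091 in each replicate share no library, and their 6 pairwise Pearson correlations across the 24242 regions were 0.213 to 0.368. The 6 matching correlations for P5091 were -0.049 to 0.12, with 4 of them below 0. With each difference freed of its trend on mean tag count the ranges were 0.166 to 0.346 and -0.042 to 0.096. Of all tested regions, 27.8% had the same sign in all 4 EPZ-6438 differences, each centred on its median, where independent signs would give 12.5%. The trend on mean tag count was left in there and can raise this share, which was not computed for P5091. The 1828 calls became 276 without P5091 replicate 1, 580 and 589 without DMSO or EPZ-6438 replicate 2, 794 without EPZ-6438 replicate 1, 1049 without DMSO replicate 1 and 2845 without combination replicate 2. Without the block, on centred libraries, limma called 38 regions (23 higher, 15 lower), and 0 on the values as deposited, with 2155 unadjusted.

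The direct comparison of the compounds at the same 7 days gave few regions. EPZ-6438 against P5091 gave 2 regions higher and 6 lower by limma with replicate block and centring, and 13 and 19 by edgeR. The lowest p values were at chr9:3490985-3491397, with tag counts of 25.2 and 37.4 with EPZ-6438 and 88.7 and 75 with P5091 (log2 difference -1.33 ± 0.26 SE, adjusted p = 0.0319), and at chr5:54506972-54507373, with 20.8 and 16.3 against 54.1 and 61.7 (-1.54 ± 0.31, adjusted p = 0.0319). The 2 higher regions were chr8:105805530-105805906 (42.9 and 39.8 against 11.7 and 14.5) and chr16:73647485-73647883 (42.9 and 33.3 against 11.7 and 11.5). This limma count was 0 without either EPZ-6438 library, without P5091 replicate 1 or without DMSO replicate 2, 1 without P5091 replicate 2, and 68 without combination replicate 1. It was also 0 with the trend removed (2096 unadjusted), with quantile normalization (1800) and without the block (907). Adding EPZ-6438 to P5091 (combination against P5091) gave 79 regions higher and 126 lower by limma, but 0 without P5091 replicate 1 (1423 unadjusted), 37 without EPZ-6438 replicate 1, 46 with the trend removed, 24 with quantile normalization and 943 without combination replicate 2; edgeR gave 65 and 80. Adding P5091 to EPZ-6438 (combination against EPZ-6438) gave 0 by limma, with 1291 unadjusted, and 0 by edgeR, with 1113 unadjusted.

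**Figure D4:**
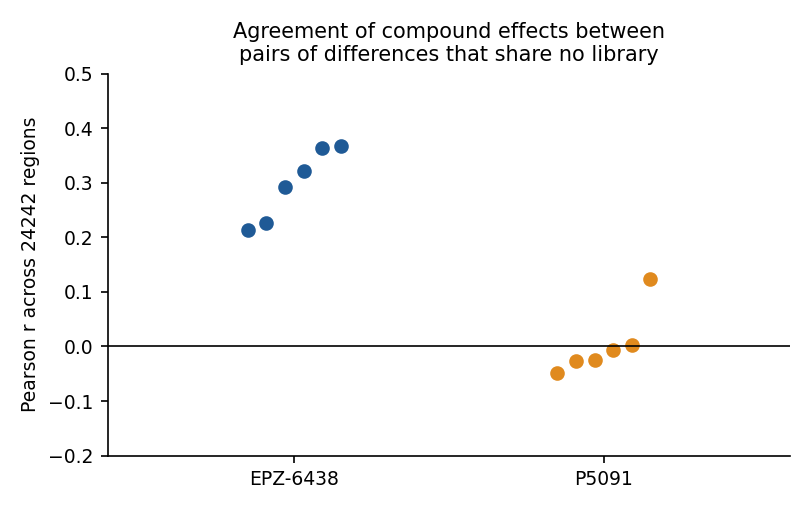
Pearson correlation across 24242 regions between differences in log2 tag count that share no library, for EPZ-6438 and for P5091; each point is a pair of differences. The 6 pairs for EPZ-6438 lie between 0.213 and 0.368 and the 6 for P5091 between -0.049 and 0.12.

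Judged by whether a peak was called at all, 4261 regions were lost with EPZ-6438 (called in both DMSO and in neither EPZ-6438 library) and 5837 gained. With P5091 3160 were lost and 2861 gained, and with the combination 7998 and 847. These counts depend on the threshold: with equal numbers of top peaks they were 1535 and 1567 for EPZ-6438, 717 and 581 for P5091 and 2149 and 1890 for the combination, and at the stricter threshold 1534 and 2289 for EPZ-6438, 933 and 978 for P5091 and 7596 and 60 for the combination, whose losses hardly moved. With replicate 1 of the treatment left out, so that a single treated library decides and gains swell for any treatment, 8286 were lost and 18848 gained with EPZ-6438, 6461 and 14774 with P5091 and 8522 and 18516 with the combination. Most of these were weak sites: the lost regions had a median tag count of 12.5 for EPZ-6438, 11.8 for P5091 and 13.1 for the combination. Sorting the same 4 libraries by replicate number in place of treatment gave counts of the same order for EPZ-6438 and larger ones on the replicate 2 side for the others, with 2243 regions called in both replicate 1 libraries alone and 5224 in both replicate 2 libraries alone for EPZ-6438 and DMSO, and 2487 and 7818 for P5091 and DMSO. For the combination they were 153 and 9541. Pairing a treated library of one replicate number with the DMSO library of the other gave 2509 and 1744 for EPZ-6438, 1708 and 2072 for P5091, and 208 and 4258 for the combination. Both replicates of a treatment were filtered against the same input, so neither sorting shows losses or gains that come from an input. How many lost or gained regions come from the input filter was not tested. Leaving out combination replicate 1, 1172 regions were called in all 3 remaining EPZ-6438 libraries and in none of the 4 without it, and 728 the other way round, against 312 and 246 for P5091. Other groupings of these 7 libraries gave as many: 1311 regions were called in the replicate 2 libraries of EPZ-6438, P5091 and the combination alone, and 1574 in the 4 libraries other than replicate 1 of DMSO, EPZ-6438 and P5091.

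Several of the strongest lost regions lay next to a gained region, and whether such pairs are separate sites or a moved summit was not tested. The strongest region lost with EPZ-6438 and with the combination, chr5:96270281-96270645 (tag counts 112.6 and 177.1 with DMSO), lies beside the strongest gained, chr5:96270693-96271057 (125.7 and 122.0 with EPZ-6438). For EPZ-6438 the same holds for chr5:114037830-114038195 and chr5:114038373-114038830. A peak of the other condition lay within 1000 bases of 321 of the lost and 281 of the gained regions for EPZ-6438, of 236 and 211 for P5091, and of 445 and 104 for the combination. Among regions with no such neighbour, a selection made after the values were seen, the strongest lost with EPZ-6438 was chr15:93160855-93161245, with tag counts of 85.6 and 51.7 with DMSO and 70.5 and 35.7 with P5091 and no call in any of the 4 EPZ-6438 libraries. The strongest gained was chr11:85194933-85195295, with 89.4 and 129.3 with EPZ-6438, which was also called with P5091 at 52.8 and 82.3 and not with DMSO or the combination. For P5091 the strongest lost regions by the planned rule were chr1:219470213-219470608 (53.4 and 52.2 with DMSO) and chr14:49945496-49945946 (50.5 and 45.3), and the 2 strongest gained lay on the contig Un_gl000220. For the combination, chr2:189231857-189232243 (87.8 and 58.1 with DMSO) was the strongest lost region with no neighbouring peak. Whether the filter against input removed a peak at any of these lost or gained regions was not tested.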

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

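At the stricter threshold, fixed beforehand like all alternatives here except where stated, peaks numbered 48214 for WT, 44980 for K295A, 545 for the pGIPZ control and 502 for shFoxA1. The share of WT peaks overlapping K295A was 76.4% at the stricter threshold, 67.8% with 0.5 of the smaller peak shared, 62.7% with centres within 100 bases and 77.0% with equal numbers of top peaks, and that of K295A peaks overlapping WT 81.9%, 80.7%, 74.7% and 77.0%. Of the WT peaks 47.2%, 40.4% and 55.4% overlapped regions of both DMSO libraries at the stricter threshold, with centres within 100 bases and with equal numbers, and of the K295A peaks 51.0%, 46.6% and 57.9%. The HA shares kept WT and K295A far above the untagged lists in each of these settings.

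Lost and gained regions at the stricter threshold numbered 1534 and 2289 for EPZ-6438 and 933 and 978 for P5091, and 7596 and 60 for the combination. With equal numbers of top peaks they were 1535 and 1567, 717 and 581, and 2149 and 1890 for the combination, where gained then neared lost. Leaving out a library in turn gave 8286 to 14452 lost and 9141 to 18848 gained for EPZ-6438, 6461 to 13441 and 5777 to 14774 for P5091, and 8522 to 30451 and 1505 to 18516 for the combination, with the lowest loss and highest gain both without its replicate 1; a single library stands for a condition there, so more regions qualify.

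The P5091 difference in peak number turned to 0.021 at the stricter threshold. Leaving out each library in turn gave -0.008 to 0.195 for EPZ-6438, -0.149 to 0.125 for P5091 and -1.302 to 0.131 for the combination, the last without its replicate 1. Over all libraries with against without the compound it gave -0.373 to 0.112 for EPZ-6438 and -0.489 to -0.011 for P5091. Median tag count changes ranged over -0.133 to 0.022, -0.079 to 0.076 and -1.287 to -0.066 for EPZ-6438, P5091 and the combination, and over -0.489 to -0.058 and -0.430 to 0.005 with against without each compound. The replicate block cannot change such differences, as each group holds a library of each replicate number. For peak number they stayed at 0.093, -0.012 and -0.59.

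For tag counts, regions called in at least 4 libraries gave 15 calls for EPZ-6438, 6 for P5091, 28 for the combination and 4 for the interaction, and the 4 libraries of the contrast alone gave 10 for EPZ-6438. The replicate block alone gave 0 calls by limma in each of the 4 planned comparisons, with 325, 21, 3878 and 244 unadjusted. The replicate block with centring, added after seeing the data, gave 167 for EPZ-6438 and 1025 for the combination, and edgeR with the block and TMM factors, added too, 391 and 781. The block with the trend on mean tag count removed gave 177 and 547, and with quantile normalization 34 and 449, both added. Leaving out a library gave 0 to 0 for EPZ-6438 and for P5091 against DMSO, 0 to 16154 for the combination and 0 to 5912 for the interaction. With EPZ-6438 against without, all added after seeing the data, gave 1073 with the replicate block and quantile normalization (567 higher), 38 with no replicate block and 276 to 2845 on leaving out a library. The P5091 counterpart gave 0 to 2. EPZ-6438 against P5091 gave 0 with no replicate block, 0 with quantile normalization, 0 with the trend on mean tag count removed, 32 by edgeR and 0 to 68 on leaving out a library. The combination against P5091 gave 0 with no replicate block, 24 with quantile normalization, 46 with the trend removed and 0 to 943, and against EPZ-6438 0 to 46. The cause of these differences was not tested.

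The tag threshold at the false discovery rate, per the file headers, was 10 to 14 in FOXA1 libraries. Whether depth limits weak regions more than strong ones was not tested. Gene list, annotation and motif alternatives were not run.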

Other observations

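Every test below was chosen only after the pattern it bears on had been seen, except the comparison with input tags and that with the K295A ratio, whose outcome was fixed as a prediction first.

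EPZ-6438 differences were shared by neighbouring regions. Tested regions up to 5 kb apart had differences that correlated with r = 0.236 over 1219 adjacent pairs, with the trend on mean tag count removed, against at most 0.068 in 200 permutations. At 5 to 20 kb r was 0.106, at 20 to 100 kb 0.091 and at 100 to 1000 kb 0.072, each above the highest permuted value (0.045, 0.028 and 0.033). For P5091 the values were 0.052, -0.004, 0.004 and 0.025, of which the last alone lay above its highest permuted value, 0.024. By chromosome, the median EPZ-6438 difference lay between -0.050 on chromosome 22 and 0.038 on chromosome 18; chromosome 8 held 55 regions that rose and 34 that fell, and chromosome 6 held 40 and 79. Pairs and regions are not independent replicates.

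The untagged HA libraries had strong background peaks. The highest was at chr1:121485069-121485321, with a tag count of 10268.7 in the pGIPZ control and 9955.3 at the same site with shFoxA1, and it was called in the WT and K295A libraries too. Of the pGIPZ control peaks, 57.9% overlapped a shFoxA1 peak.

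Replicate 1 of the combination held 30811 peaks and low tag counts. Shallow sequencing is argued against, since its 15999804 tags exceed those of FOXA1 libraries with far more peaks, down to 12299238. A fall of the scaled tag counts in both replicates of the combination is argued against as well. At the regions called in all 8 libraries, replicate 2 differed from its DMSO library by 0.012 in median log2 tag count. Tag counts are scaled to each library's total, so a loss of FOXA1 that this scaling hides is not excluded. Nor is a loss outside these regions. Poorer enrichment of the replicate 1 immunoprecipitate remains possible, with 5.26% of tags in peaks. A loss of FOXA1 in that sample alone would give the same value, and with 1 such library the explanations cannot be told apart.

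The 1828 regions called between all libraries with and all without EPZ-6438 are the pattern most worth following up, as a hypothesis. With the replicate block, a fit of these groups alone called 2122 regions and the highest of the other 17 balanced splits 0, but 18 splits are too few for a share under 0.05, as 1 of 18 gave as many. Without the block, 3 of 35 splits gave at least the real 324, so chance is not excluded there; the highest of the others, 1565, set DMSO, EPZ-6438 and P5091 replicate 1 with DMSO replicate 2, and another, 574, followed the replicate number. A trend on peak strength as the whole cause is argued against, since 1152 of the 1828 were called again once it was removed. Input tags at regions that rose were higher by 0.17 on the log2 scale (bootstrap interval over regions 0.104 to 0.234). FOXA1 rose there by a median of 0.82, and the upper bound lay below it by the margin predicted for inputs that are not the cause. However, each treatment has 1 input for both replicates, and the interval leaves out the spread between inputs. The tested regions had also passed a filter against input. A contribution of the inputs is therefore not excluded. A change of FOXA1 at particular regions upon EZH2 inhibition may underlie the remaining calls, and differences between the treated samples that have nothing to do with EZH2 stay open.

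For P5091 the matching fit called 0 regions, so all 18 splits gave as many by definition and this comparison says nothing about P5091; the highest other count, 2122, was the EPZ-6438 split.

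If EPZ-6438 and the K295A substitution acted on FOXA1 at the same regions, the ratio of K295A over WT should follow the EPZ-6438 difference. Over 21026 regions in both HA lists the correlation was -0.023 with trends on peak strength removed, inside the range of 1000 circular shifts (-0.029 to 0.023), so no such relation was seen. The median log2 ratio of K295A over WT was -0.073 at regions that rose with EPZ-6438, -0.044 at those that fell and -0.032 at all tested regions. The HA ratio rests on 1 library per protein, which limits what this comparison can show.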
